A study of Mus musculus with 24 samples.

How the data were processed

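Single cells of the cerebral cortex were profiled from 24 mice that carry 5xFAD, a set of familial Alzheimer's disease transgenes that leads to amyloid deposits in the brain. Per the labels, the mice also carry Cx3cr1CreER, which puts a tamoxifen-dependent Cre recombinase under a promoter active in microglia, and a TREM2 transgene in its WT or its R47H form. TREM2 is a lipid-sensing receptor of microglia, and R47H is a variant of it linked to Alzheimer's disease risk. Tamoxifen at 2 months of age switched the transgene on in the induced mice, and the control mice were given the oil alone. Each of the 4 groups (WT control, WT induced, R47H control, R47H induced) held 6 mice, 1 library per mouse by the labels, so tests measure the spread between animals. Groups were taken from the genotype and treatment labels and replicate numbers run in label order. The design text puts both sexes in every group, but the sex of each mouse is not given in the sources used here. Induction and tamoxifen always came together, so no comparison here can separate them.

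Per the labels' protocols, perfused cortex was dissociated with enzymes at body temperature, followed by bead removal of myelin, lysis of red cells and removal of dead cells, with no sort for microglia. Libraries were made with the Chromium 3' version 3 chemistry and sequenced on a HiSeq instrument. The values are whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, as the authors deposited them. Per the submitters' processing notes, Cell Ranger (version not given in the sources used here), Seurat 3.1 and the mouse build mm10 were used. Whether the counting used strand is not given in the sources used here. The lowest UMI total of a barcode was 500, and the lowest in each library was at most 506. Gene positions, 1-based on mm10, come from the GENCODE annotation of mouse release 21, which placed 30934 (99.6%) of the 31053 genes by identifier. The gene table held 0 identifiers of another species, so transgene transcripts of human sequence were not measured, and Clec7a had no entry and is not analysed here.

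Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrially encoded genes. This left 80206 (31.1%) of 257991 barcodes. Doublets were scored per library with scrublet as built into scanpy. Its automatic limit marked almost no cell in several libraries, so a score limit of 0.25 was set for all libraries after seeing the data, which removed 1760 cells (2.19%) and left 78446. Up to 1500 cells per library (30850 in all) were clustered on 2497 variable genes without Trem2, sex-linked or mitochondrially encoded genes, with 30 principal components, 20 neighbours and Leiden resolution 1. The other cells took the cluster of most of their 15 nearest neighbours. A cluster was called "X-like" when at least 3 markers of a fixed list were seen in at least 10% of its cells, the markers reached at least 0.2 of their level in the cluster that was highest for them, and no other type reached over 0.5 of the leading type's ratio. The limit of 0.2 was lowered from a first choice after seeing the data. The lists covered microglia, border macrophages and other immune cells, astrocytes, oligodendrocytes and their precursors, vascular, ependymal and choroid plexus cells, neurons, progenitors and erythroid cells. Of 28 clusters, 10 were microglia-like, and no cluster was oligodendrocyte-like.

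UMI counts were summed per library over the cells of a type. These sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion, TMM factors and filterByExpr, with 1 mean per group and all 24 libraries in one model. The 5 comparisons were the WT induction, the R47H induction, the difference between the inductions (interaction), and R47H against WT in control and in induced libraries. Benjamini-Hochberg adjusted p-values below 0.05 were called. Types other than microglia needed at least 20 cells per library and at least 3 such libraries per group. Astrocyte-like cells met this only under a loose filter (300 genes, 500 UMIs, 25% mitochondrial), added after seeing the data, and endothelial-like cells met it in 4 libraries per group. Group levels are means of CPM (UMIs scaled to a common TMM-adjusted library total) ± SD over 6 libraries, and folds are log2 with the standard error (SE) of the model. Counts were simulated from the real means and depths, so other structure of the libraries is not covered. Of 50 genes each changed by 2, 4, 8 and 16 times, WT induction in microglia recovered 66%, 96%, 96% and 100% (6 false of 185 calls, 9478 genes). R47H against WT controls gave 56%, 92%, 100% and 100% (8 false of 182, 9468 genes). WT induction gave 14%, 72%, 90% and 94% in endothelial cells (5 false of 140, 1893 genes). In astrocytes under the loose filter it gave 46%, 96%, 98% and 100% (8 false of 178, 9053 genes).

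Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list moves one way by itself. In microglia 19 gene lists were tested: homeostatic, DAM stage 1 and stage 2 (disease-associated microglia), TREM2 signalling, interferon response, MHC class II, MHC class I, cytokines and chemokines, proliferation, lysosome, phagocytosis and complement, lipid handling, cholesterol synthesis, glycolysis, oxidative phosphorylation, immediate early, heat shock, ribosomal protein and mitochondrially encoded genes. Beside them stood 5 marker lists of other cells (monocyte, astrocyte, oligodendrocyte, endothelial, choroid plexus). Lists of reactive and homeostatic astrocytes, the blood-brain barrier and endothelial activation were tested in their own cells. Oligodendrocyte lists (disease-associated, myelin) had no cluster to test. Some genes stand on 2 lists, such as Apoe, Lpl and Npc2. In simulated WT induction in microglia, a list raised 2 times gave p = 2.86e-41 (4.5e-12 with an estimated correlation). For 1 unchanged list p was 0.68, which leaves the preset value untested on correlated genes.

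Shares of cells per library were compared with two-sided exact permutation tests over all 924 relabellings of 6 against 6, whose smallest possible p is 0.00216. In simulations 4.2% of null differences fell below 0.05 and 99.5% of shifts of 3 SD did. For the DAM-high share, each microglia-like cell was thinned to 1000 UMIs and called DAM-high when more UMIs fell on 12 DAM score genes (Cst7, Lpl, Itgax, Spp1, Gpnmb, Axl, Csf1, Cd9, Cd63, Lgals3, Ccl6, Apoe) than on 9 homeostatic genes (P2ry12, Tmem119, Cx3cr1, P2ry13, Selplg, Siglech, Gpr34, Fcrls, Olfml3). This is a range of a score, not a cell type.

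Genes were named by a rule. Trem2 came first. Then up to 10 genes per direction and comparison were taken by fold among those called, with a mean of at least 10 CPM in either group and at least 5 of 6 libraries of the first group on the same side of the second group's mean. Where under 5 passed in a direction, all were named and genes with the smallest p could be added as not passing. Up to 4 members per list with the smallest p served as examples. Sex-linked, mitochondrial and ribosomal genes outside their lists and predicted genes were counted and not named. Other genes named were chosen after their values were seen, and this is said where they stand.

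Groups, comparisons, tests, gene lists, the naming rule and a first set of alternatives were fixed before the data were examined. That set was DESeq2 1.42.0 and limma voom with quality weights in place of edgeR, RLE scaling, no filter or at least 10 CPM, only the groups compared, stricter cells (2000 UMIs, 5% mitochondrial), doublets kept, thinning to equal depth, the library quartet as a replicate block, Xist as a covariate, other settings of the DAM score, and each library left out. Xist stood in that set for genes and not for lists. Alternatives added after seeing the data are listed below, such as leaving out the 4 deepest libraries or giving them a term, alone or with the block. The labels give no number that groups share. Library numbers run through the groups in quartets of 1 library per group, and deviations from group means were correlated within quartets over 3295 genes. All 6 pairs were above 0.1 for R47H control with R47H induced (0.216 to 0.894) and for WT induced with R47H induced libraries (0.137 to 0.924). With WT control libraries 4 of 6 pairs were, for each other group. Values with the block therefore stand beside the R47H induction and the induced line comparison where they change a call or a count. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.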

Results

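Droplet single-cell RNA sequencing of the cortex was used to compare 4 groups of 6 5xFAD mice in the middle stage of amyloid deposition. The groups were the TREM2-WT and the TREM2-R47H line, each without (control) and with induction (induced). Libraries, 1 per mouse by the labels, held between 14329115 and 73898385 UMIs (median 20041466). WT control 2 was high in both Xist (1851.9 CPM in microglia-like cells) and Y genes (116.6 CPM), so that it holds cells of 1 mouse is left open. In each group 1 library was far deeper than the others: WT control 2 (59657125), WT induced 1 (64114812), R47H control 1 (57319503) and R47H induced 1 (73898385), against at most 25082589 elsewhere. In these 4 libraries 63.2% to 83.0% of barcodes passed the cell filters, against 7.48% to 33.7% in the other 20, and they held 57.4% of the cells used. Values without these 4 libraries, 5 against 5, are therefore given beside the pooled ones. A single deep library per group is too few for a test within them.

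**Figure D1:**
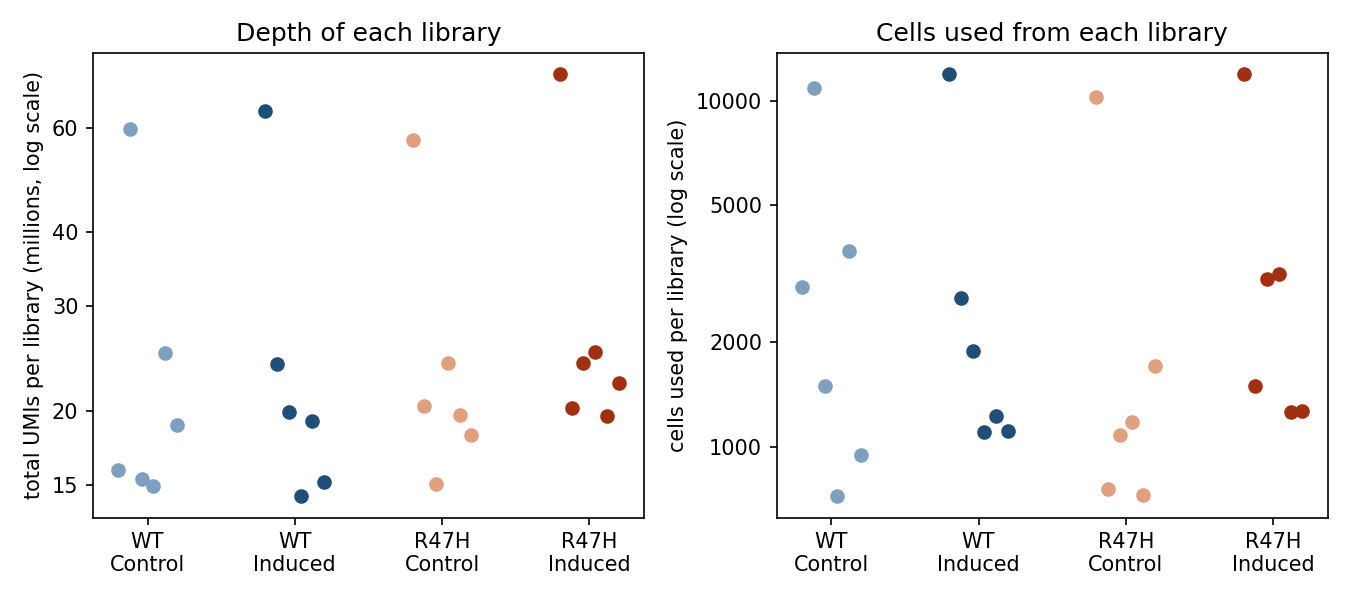
Total UMIs (left) and cells used (right) per library, both on log axes, for the 6 libraries of each group, 1 point per library. The deepest library of each group stands at 57319503 UMIs or more and the other libraries at 25082589 or fewer, and cells used run from 717 to 11933.

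After the filters 78446 cells remained, 717 to 11933 per library. Microglia-like cells were the largest class, with 15552 in WT control, 13080 in WT induced, 10095 in R47H control and 13717 in R47H induced libraries. Of the 10 microglia-like clusters, the largest (16791 cells, led by Slc2a5, Crybb1 and Tmem119) came almost entirely from the 4 deep libraries. Other clusters were led by Fos (8734 cells), Hspa1b and Hk2 (8136), Ccl4, Ccl2 and Tnf (6182), Cst7 and Igf1 (4443), Cxcl10 and Isg15 (669), and Mki67 and Top2a (457). A cluster of 3969 cells led by Cxcl13, Cd74, H2-Q7 and H2-Ab1 took 96.7% of its cells from R47H induced 1, and a cluster of 2020 cells led by Lpl, Igf1 and Spp1 took 82.9% from WT control 2. Endothelial-like (10826 and 596 cells), astrocyte-like (4065), mural-like (1060) and choroid plexus-like clusters were also found. The summed microglia-like cells gave 1208245 to 27775810 UMIs per library, over which 9663 genes were tested.

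Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147 on mm10, protein coding), the endogenous gene that matches the transgene, did not pass the test in any comparison. Its mean in microglia-like cells was 1997 ± 654 CPM in WT control (SD, n = 6, range 1127 to 2633), 1465 ± 209 in WT induced (1222 to 1714), 1917 ± 259 in R47H control (1530 to 2179) and 1954 ± 684 in R47H induced libraries (1083 to 2738). The log2 fold was -0.45 (SE 0.24) on WT induction and 0.03 (SE 0.24) on R47H induction, with a difference of 0.47 (SE 0.34) between them. R47H against WT gave -0.06 (SE 0.24) in controls and 0.42 (SE 0.24) in induced libraries (adjusted p = 1 in each of the 5 comparisons). The gene table holds mouse genes, so these values say nothing of transcripts of human TREM2.

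The first comparison asked what induction of the WT form changed in microglia. Setd5, a gene for a SET domain chromatin protein (ENSMUSG00000034269, chromosome 6, 113077365 to 113153435, mm10, protein coding), rose from 83.2 ± 14.1 to 178 ± 22.4 CPM (SD, n = 6 and 6; log2 1.10, SE 0.15, adjusted p = 0.000856), with 6 of 6 induced libraries above the control mean. It was the 1 gene of 9663 that passed. Its upstream neighbour Thumpd3, a tRNA methyltransferase gene (ENSMUSG00000030264, 113046225 to 113068273), had the next smallest p, with 27.9 ± 8.19 and 59.8 ± 11.7 CPM (log2 1.07, SE 0.21, adjusted p = 0.13, 6 of 6 libraries higher). The antisense RNA gene between them, Gt(ROSA)26Sor (ENSMUSG00000086429, 113067428 to 113077333, chosen after its values were seen), stood at 16.1 ± 8.86 and 32.3 ± 15.98 CPM (log2 0.996, SE 0.64, adjusted p = 1). It overlaps the end of Thumpd3, so UMIs of these genes may be shared between them.

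Other genes with small p on WT induction did not pass. Bank1, a B cell scaffold gene, had log2 1.11 (SE 0.24, adjusted p = 0.25). The prostaglandin receptor Ptger3 stood at 1.76 and the chemokine Ccl9 at 0.84 (adjusted p = 1 each). On the lower side Postn, a matrix protein, had log2 -2.21 (SE 0.45), Ttpal -1.11 (SE 0.23, adjusted p = 0.13 for each) and the ceramide synthase Cers6 -0.85 (0.926). With the 4 deep libraries left out, Setd5 had log2 1.06 (SE 0.13, adjusted p = 0.00036) and 3 genes passed. Setd5 lost its call under the stricter cell filter (log2 1.30, adjusted p = 0.999) and ranged down to 9.65e-09 over 28 alternatives. Without WT control 2 the count was 3, with Setd5, Thumpd3 (1.21) and Ttpal (-1.24, adjusted p = 0.0325 each). Without WT control 5 it was 2, with Postn at -2.43 (adjusted p = 0.039).

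On WT induction the gene groups of activated microglia were lower and interferon genes higher than in control libraries. All 16 tested DAM stage 2 genes were lower (median log2 -0.98, adjusted p = 2.8e-09; adjusted p = 0.52 with an estimated correlation), 1 of them passing adjusted over the list alone. Examples were Spp1 (70.0 ± 71.9 and 9.75 ± 8.34 CPM, log2 -2.77, SE 0.83), the integrin Itgax (-2.19, SE 0.73), the lipase Lpl (-1.61, SE 0.57) and Gpnmb (-2.30, SE 0.96), each with adjusted p = 1 over all genes. Of 7 DAM stage 1 genes 6 were lower (median -0.46, adjusted p = 0.00787; adjusted p = 0.52 with an estimated correlation), among them Apoe (-1.56, SE 0.68), Lyz2 (-1.11, SE 0.51) and Tyrobp (-0.46, SE 0.32). All 18 lysosome genes (median -0.33, adjusted p = 3.13e-05, such as Cd63 at -0.65), 9 of 12 lipid handling genes (-0.34, adjusted p = 0.00445, such as Fabp5 at -1.96) were lower, and so were 10 of 10 glycolysis genes (-0.37, adjusted p = 0.00379, such as Ldha at -0.40). Each of these 3 had adjusted p = 0.52 with an estimated correlation. Oxidative phosphorylation (22 of 22 lower, median -0.19, adjusted p = 0.00411) and ribosomal protein genes (74 of 74, -0.22, adjusted p = 5.64e-06) fell, each with adjusted p = 0.632 with an estimated correlation, and mitochondrially encoded genes (13 of 13, -0.18, adjusted p = 0.0225) with adjusted p = 0.64 with an estimated correlation.

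All 14 interferon response genes were higher on WT induction (median 0.66, adjusted p = 6.11e-05; adjusted p = 0.52 with an estimated correlation), such as Rtp4 (0.72, SE 0.24) and Ifitm3 (0.72, SE 0.48). MHC class I genes were higher in 8 of 9 (0.36, adjusted p = 0.0225; adjusted p = 0.632 with an estimated correlation), such as H2-Q7 (1.93, SE 0.85). Proliferation genes were higher in 13 of 14 (0.27, adjusted p = 0.00187; adjusted p = 0.52 with an estimated correlation), such as Ccnb2 (0.997, SE 0.51). Among the 20 other libraries, the interferon (median 0.79, adjusted p = 1.97e-05), proliferation (0.43, 0.0157) and MHC class I calls (0.32, 0.033) stood. So did those of lysosome (-0.15, 0.024), glycolysis (-0.13, 0.0432), oxidative phosphorylation (-0.14, 0.0196), ribosomal (-0.18, 3.7e-05) and mitochondrial genes (-0.14, 0.0214). DAM stage 2 then had a median of -0.23 (adjusted p = 0.0362), while DAM stage 1 (-0.26, 0.392) and lipid handling (-0.049, 0.438) no longer passed. Heat shock genes then passed (-0.53, 0.0118; -0.22 and 0.0745 over all libraries). Each of the 10 lists that then passed had adjusted p = 0.817 with an estimated correlation. Of 24 lists 11 passed with all libraries, 6 without WT induced 1, 7 without WT control 2 and 7 without WT control 6.

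Lists that did not pass on WT induction were MHC class II (median 0.66, adjusted p = 0.603, 6 of 6 genes higher, such as H2-Eb1 at 1.69), homeostatic genes (-0.0031, 0.585, mean 0.0097), phagocytosis and complement (-0.12, 0.38) and cholesterol synthesis (-0.069, 0.167). TREM2 signalling had a median of 0.03, a mean of -0.025 and a lower test direction (0.968), and immediate early genes 0.044, -0.077 and a lower direction (0.463). Cytokines and chemokines had a median of -0.076, a mean of 0.089 and a higher test direction (0.819), with Cxcl16 at -0.59 and Ccl7 at 1.48. Among markers of other cells, the median was -0.15 for astrocytes (0.157), 0.14 for oligodendrocytes (0.525), -0.11 for endothelial cells (0.692, with a higher test direction), 0.68 for monocytes (0.472) and 1.55 for choroid plexus (0.472).

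The second comparison asked the same of the R47H form. Setd5 again rose, from 80.8 ± 15.9 to 146 ± 21.5 CPM (SD, n = 6 and 6; log2 0.85, SE 0.15, adjusted p = 0.0243, 6 of 6 libraries higher). Adgrg5, an adhesion G protein-coupled receptor gene (ENSMUSG00000061577, chromosome 8, 94923694 to 94943280), was the other gene that passed (log2 4.62, SE 0.79, adjusted p = 0.0243, 5 of 6 libraries higher), at means of 0.0293 and 3.31 CPM, under the level of 10 CPM set for naming. Thumpd3 stood at 27.6 ± 9.33 and 42.2 ± 7.52 CPM (log2 0.59, SE 0.21, adjusted p = 1) and Gt(ROSA)26Sor at 10.0 ± 7.73 and 21.4 ± 10.9 CPM (log2 1.22, SE 0.70, adjusted p = 1). Genes with small p that did not pass included Ccdc122 (1.23, SE 0.28, adjusted p = 0.521), Ccl9 (1.08, 0.737) and H2-Q7 (3.08, SE 0.81, 0.834) on the higher side. On the lower side stood the protease Ctse (-3.17, SE 0.73, 0.521) and the scavenger receptor Colec12 (-3.20, 0.737).

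**Figure D2:**
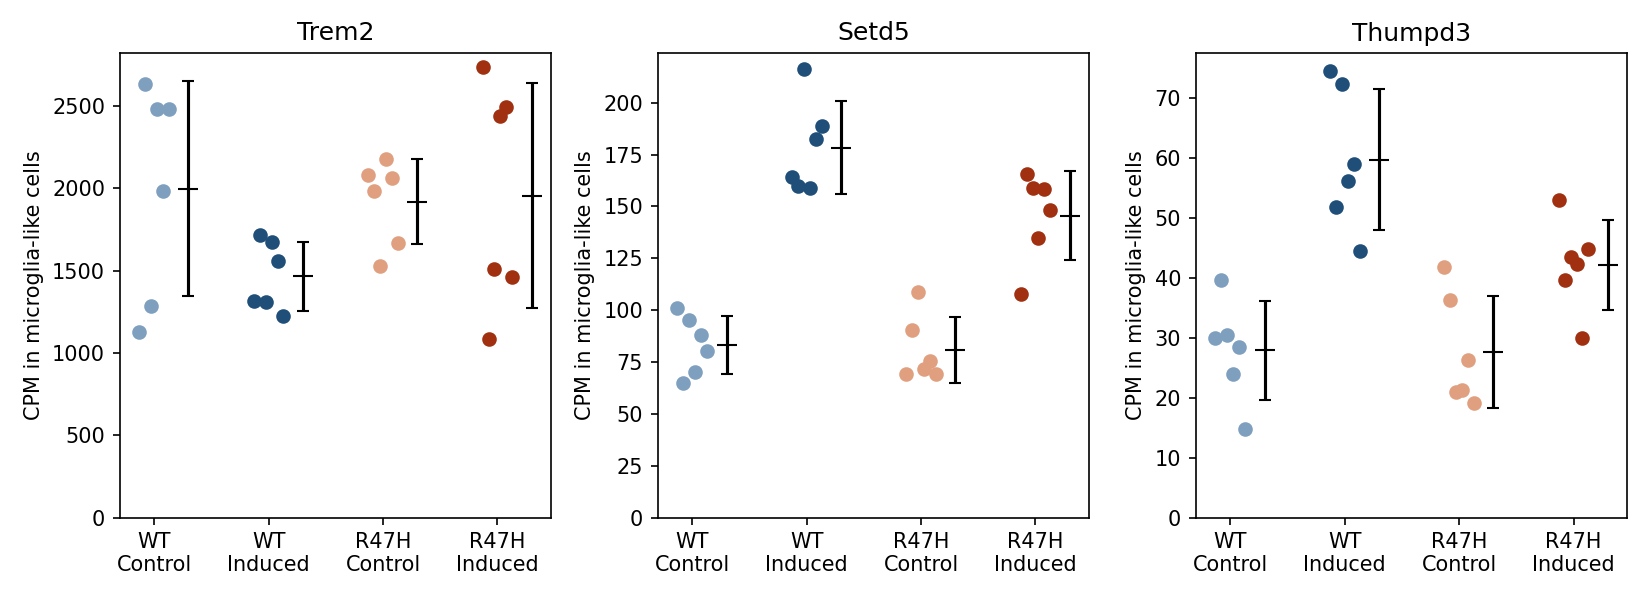
Trem2, Setd5 and Thumpd3 in summed microglia-like cells, in CPM per library, for the 4 groups of 6 libraries, with black bars for mean ± SD. Setd5 spans 65.0 to 101 CPM in WT control and 159 to 216 in WT induced libraries, while the ranges of Trem2 overlap between all groups.

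In the 20 libraries other than the deep ones, Setd5 had log2 0.87 (SE 0.14, adjusted p = 0.00953) on R47H induction and 1 gene passed. Over 28 alternatives its fold stayed between 0.81 and 0.95 and its adjusted p between 3.01e-05 and 1. The call ended with only the R47H groups in the fit (0.906), under the stricter filter (1) and under the loose filter (0.0509). The call of Setd5 ended without any of R47H control 1, 2, 4, 5 and 6 (adjusted p = 0.0507 to 0.214) and R47H induced 2 to 6 (0.063 to 0.139). It stood without R47H control 3 (0.0123) and R47H induced 1 (0.0109). Adgrg5 held its call in 9 of 22 alternatives (adjusted p 0.000592 to 0.568) and, among libraries left out, without R47H induced 2. The count of passing genes, 2 with all libraries, was 1 without R47H control 3, R47H control 6, R47H induced 1 or R47H induced 2, and 0 without any other R47H library. Without R47H control 6 the gene was Gnb4, chosen after its values were seen (log2 6.10, SE 0.48, adjusted p = 5.89e-08; 2.34, SE 0.74, adjusted p = 1 with all libraries). With the library quartet as a replicate block 1 gene passed, Setd5 (0.86, adjusted p = 0.0131), and Adgrg5 did not (0.0787).

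Antigen presentation genes rose on R47H induction. All 6 MHC class II genes were higher (median log2 2.01, adjusted p = 3.02e-08; adjusted p = 0.244 with an estimated correlation; 1 passing adjusted over the list alone), among them H2-DMa (0.81, SE 0.24), Cd74 (2.49, SE 0.99), H2-Ab1 (2.08, SE 0.87) and H2-Eb1 (2.20, SE 1.02). All 9 MHC class I genes were higher (0.86, adjusted p = 3.02e-08; adjusted p = 0.288 with an estimated correlation; 4 adjusted over the list alone), such as H2-Q7, H2-K1 (1.33, SE 0.41), H2-D1 (1.47, SE 0.52) and the immunoproteasome gene Psmb9 (0.68, SE 0.22). H2-Q genes are near-identical copies of each other, so single values for them are uncertain. Immediate early genes were higher in 14 of 16 (0.16, adjusted p = 0.032; adjusted p = 0.856 with an estimated correlation), such as Nr4a1 (0.47, SE 0.25), a call that ended without R47H induced 1 (0.099, 0.0827) and with Xist as a covariate (0.12, 0.0661). MHC class II stood at 1.12 (adjusted p = 0.00197) and MHC class I at 0.36 (0.00567) without R47H induced 1.

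On R47H induction 8 lists passed without the 4 deep libraries, in place of 3, with adjusted p = 0.855 to 0.928 with an estimated correlation. Those on the higher side were MHC class II (median 1.01, adjusted p = 0.00412), MHC class I (0.38, 0.00135) and immediate early genes (0.18, 0.00516). Those on the lower side were choroid plexus markers (-1.12, 0.00705), DAM stage 2 (-0.37, 0.00412), proliferation (-0.32, 0.00705), lysosome (-0.14, 0.00516) and lipid handling (-0.11, 0.00792). Over all libraries the last 5 had -1.07 (0.0538), -0.20 (0.084, 11 of 16 lower), -0.15 (0.108), 0.0061 with a lower test direction (0.246) and -0.046 (0.159). With the quartet as a replicate block 5 lists passed, choroid plexus markers (-1.38, 0.019) and ribosomal genes (0.11, 0.0201) beside the former 3, these 2 at adjusted p = 0.456 and 0.927 with an estimated correlation. The number of passing lists was 10 without R47H control 1, 5 without R47H control 2, 6 without R47H control 3 or R47H control 6, 8 without R47H induced 1 (adjusted p = 0.69 to 0.723 with an estimated correlation), and 7 without R47H induced 2 or R47H induced 5. Newly called without R47H induced 1 were DAM stage 2 (-0.19, 0.0424), proliferation (-0.23, 0.0435), lysosome (-0.175, 0.00567), oxidative phosphorylation (0.165, 0.00599), ribosomal (0.23, 1.77e-06) and mitochondrial genes (0.17, 0.0138), and ribosomal genes with Xist (0.155, 0.00034; adjusted p = 0.931 with an estimated correlation). Lists that passed neither with all libraries nor without the deep ones were homeostatic (-0.051, 0.806), DAM stage 1 (-0.016, mean 0.045, 0.77), TREM2 signalling (0.015, lower direction, 0.988), interferon (0.24, 0.362), cytokines and chemokines (0.28, 0.126) and phagocytosis (0.039, 0.77). The same held for cholesterol synthesis (0.079, mean -0.013, 0.974), glycolysis (0.044, lower direction, 0.77), oxidative phosphorylation (0.028, 0.77), heat shock (-0.32, 0.299), ribosomal (0.086, 0.084) and mitochondrial genes (0.0082, mean -0.028, 0.974), and monocyte markers (-0.018, higher direction, 0.903).

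The third comparison asked whether the inductions differed between the lines. No gene passed with edgeR (smallest adjusted p = 1; 77 genes at unadjusted p under 0.05 against 483 by chance), and 0 passed with DESeq2 and with voom. Small p were those of Adgrg5 (difference of log2 folds 4.12, SE 0.93) and Ccdc122 (1.44, SE 0.38) toward R47H. Toward WT they were those of Nsmaf (-0.75, SE 0.22), Ptger3 (-2.33, SE 0.72), Oser1 (-1.23, SE 0.42) and Bank1 (-0.95, SE 0.34), and adjusted p = 1 held for each of these genes. Without R47H control 6 the count was 1, Gnb4 (6.63, SE 0.68, adjusted p = 1.15e-05; 2.86, SE 1.34, adjusted p = 1 with all libraries).

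Of 24 lists 10 differed between the inductions, and none with an estimated correlation (adjusted p from 0.57 to 0.655 for these 10). Differences toward R47H were seen for DAM stage 2 (15 of 16 genes, median 0.71, adjusted p = 0.00309, such as Spp1 at 2.27, SE 1.09), MHC class II (6 of 6, 0.64, 0.000185, such as Cd74 at 2.47, SE 1.34) and MHC class I (9 of 9, 0.50, 0.0173). They were seen also for lysosome (17 of 18, 0.32, 0.035), oxidative phosphorylation (22 of 22, 0.21, 0.00758), ribosomal protein (74 of 74, 0.30, 1.79e-07) and immediate early genes (13 of 16, 0.18, 0.0101). Differences toward WT were seen for proliferation (12 of 14, -0.43, 0.000112, such as Ccnb2 at -1.62, SE 0.69), interferon response (10 of 14, -0.38, 0.0337) and choroid plexus markers (-2.75, 0.0199). The 5 lists that passed without the 4 deep libraries were interferon (-0.69, 2.88e-06), proliferation (-0.66, 3.17e-05), ribosomal (0.23, 0.000711), immediate early (0.23, 0.0012) and choroid plexus (-2.72, 0.0346), with adjusted p = 0.606 to 0.91 with an estimated correlation. DAM stage 2 then stood at 0.12 with a lower test direction (0.619) and MHC class II at -0.22 with a higher one (0.168), and MHC class I (0.056, 0.379), lysosome (0.023, 0.717) and oxidative phosphorylation (0.13, 0.163) lost their calls. Without R47H induced 1 alone MHC class II stood at 0.052 with 3 of 6 genes higher (0.0307), MHC class I (-0.09, higher direction, 0.668) and lysosome (0.099, 0.668) lost their calls, proliferation was at -0.70, oxidative phosphorylation at 0.35 and mitochondrial genes passed (0.35, 0.000108). With Xist interferon lost its call (-0.33, 0.137), MHC class II was at 1.87 (4.1e-05), and DAM stage 1 (0.46, 0.0148), glycolysis (0.45, 0.0193) and mitochondrial genes (0.32, 0.0163) passed. None of these passed with an estimated correlation (smallest adjusted p = 0.522). Without R47H control 3, 6 lists passed.

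The fourth comparison set the R47H line against the WT line without induction. Of 9663 genes 5 were higher and 4 lower in R47H. Ifi202b, an interferon-inducible gene of the p200 family (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), had 0 UMIs among 39138218 in WT control and 178 in R47H control libraries. Its mean in R47H was 13.2 ± 9.47 CPM (adjusted p = 0.00571), and a count of 0 allows up to 3 UMIs (0.0767 CPM) over the WT group. Rnaset2b, a ribonuclease gene with near-identical copies and so uncertain (ENSMUSG00000094724, chromosome 17, 6970634 to 7011299), rose from 5.60 ± 1.27 to 98.1 ± 37.7 CPM (log2 4.08, SE 0.62, adjusted p = 0.0042). Ccdc80, a secreted matrix protein (ENSMUSG00000022665, chromosome 16, 45093402 to 45128077), rose from 2.06 ± 1.31 to 19.5 ± 12.6 CPM (3.30, SE 0.55, 0.00601). The Cdc42 effector Cdc42ep3 (ENSMUSG00000036533, chromosome 17, 79333727 to 79355091) rose from 6.76 ± 2.47 to 18.97 ± 5.09 CPM (1.48, SE 0.28, 0.0326). Pcp4, a calmodulin-binding protein (ENSMUSG00000090223, chromosome 16, 96467606 to 96525793), fell from 37.5 ± 13.1 to 8.13 ± 4.99 CPM (-2.34, SE 0.46, 0.0356). The calcium channel subunit Cacna1a (ENSMUSG00000034656, chromosome 8, 84388440 to 84640246) fell from 81.8 ± 26.5 to 26.2 ± 14.2 CPM (-1.69, SE 0.32, 0.0326) and the DNA repair nuclease Ercc5 (ENSMUSG00000026048, chromosome 1, 44147744 to 44181260) from 38.5 ± 7.01 to 21.2 ± 2.34 CPM (-0.86, SE 0.17, 0.0332). Each of these 7 protein-coding genes had 6 of 6 R47H libraries on the same side of the WT mean.

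Epb41l3 (2.69, SE 0.41, adjusted p = 0.0042) and Adgrg5 (-4.86, SE 0.79, 0.00571) also passed, at means under 10 CPM. With the deep libraries left out 33 genes passed. Cacna1a then lost its call (log2 -1.34, adjusted p = 0.111; 0.000361 to 0.465 over 28 alternatives), while the other named genes stood, at 3.23 for Ccdc80, 4.04 for Rnaset2b, 1.83 for Cdc42ep3, -2.13 for Pcp4 and -0.90 for Ercc5.

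The count of 9 genes between control libraries became 5 without WT control 5, R47H control 5 or R47H control 6. The call of Cacna1a ended without WT control 2, 4 or 5 (adjusted p = 0.0606 to 0.0701) or R47H control 1, 2, 3, 5 or 6 (0.0597 to 0.112). That of Cdc42ep3 ended without WT control 1, 3 or 5 (0.0941 to 0.118) or R47H control 2, 3, 5 or 6 (0.0686 to 0.0981). That of Pcp4 ended without any library of the comparison (adjusted p 0.0677 to 0.123) other than WT control 2, WT control 6 and R47H control 4. That of Ercc5 ended without any other than WT control 2 and WT control 6 (up to 0.124). Adgrg5 lost its call without R47H control 1 (0.0705). With only the control groups in the fit, Cdc42ep3, Pcp4 and Cacna1a (0.0808 each) and Ercc5 (0.0723) lost theirs, and under the loose filter the same 4 (0.0605, 0.46, 0.32 and 0.0605) and Epb41l3 (0.0605) did. Ifi202b lost it after thinning (0.0639) and with a term for the deep libraries (0.0515). Over 27 alternatives adjusted p ran from 0.000831 to 0.118 for Cdc42ep3, 0.00044 to 0.46 for Pcp4 and 0.00622 to 0.124 for Ercc5.

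Interferon and antigen presentation genes were higher in R47H than in WT controls. Of 14 interferon genes 13 were higher (median log2 1.18, adjusted p = 3.17e-13; adjusted p = 0.163 with an estimated correlation), 8 passing adjusted over the list alone, such as Ifit2 (1.69, SE 0.46) and Bst2 (0.88, SE 0.26). All 6 MHC class II genes (2.19, adjusted p = 7.26e-06; adjusted p = 0.237 with an estimated correlation; 3 adjusted over the list alone), were higher, such as H2-Aa (21.8 ± 13.2 and 271 ± 432 CPM, log2 3.64, SE 1.05). So were 9 of 9 MHC class I genes (0.42, adjusted p = 0.0079; adjusted p = 0.62 with an estimated correlation) and 12 of 14 proliferation genes (0.50, adjusted p = 0.000375; adjusted p = 0.245 with an estimated correlation), such as Ccnb2 (1.53, SE 0.51). DAM stage 2 genes were higher in 12 of 16 (0.18, adjusted p = 0.00189; adjusted p = 0.699 with an estimated correlation). All 16 immediate early genes were lower (-0.30, adjusted p = 4.06e-06; adjusted p = 0.163 with an estimated correlation; 2 adjusted over the list alone), such as Klf6 (-0.56, SE 0.18) and Fos (-0.71, SE 0.33). So were 13 of 15 homeostatic genes (-0.16, adjusted p = 0.00797; adjusted p = 0.245 with an estimated correlation), such as Gpr34 (-0.37, SE 0.16). Markers of other cells moved too, with 7 of 7 astrocyte markers lower (-0.60, adjusted p = 0.000452; adjusted p = 0.237 with an estimated correlation; 1 adjusted over the list alone) and choroid plexus markers higher (2.40, adjusted p = 0.0157; adjusted p = 0.245 with an estimated correlation).

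Between control libraries 15 lists passed without the 4 deep libraries, in place of 9, and none with an estimated correlation (smallest adjusted p = 0.275, for interferon). Interferon was then at 1.36 (adjusted p = 3.62e-13), MHC class II at 2.86 (4.39e-05), MHC class I at 0.54 (0.00626) and proliferation at 0.76 (0.00221). DAM stage 2 was at 0.72 (7.09e-06), immediate early at -0.36 (8.55e-08), homeostatic at -0.20 (0.000768), astrocyte markers at -0.57 (0.00515) and choroid plexus at 2.59 (0.00943). Newly higher, with sex unbalanced, were DAM stage 1 (0.375, 0.00373), lipid handling (0.25, 0.00571), lysosome (0.22, 0.00173), glycolysis (0.29, 0.00263), oxidative phosphorylation (0.11, 0.0117) and ribosomal genes (0.14, 4.4e-05). Over all libraries their adjusted p was 0.169 to 0.906. Without WT control 2 the count was 14, and with Xist DAM stage 2 was at 0.38 (0.000634). Over all libraries medians, means or test directions differed in sign for 4 lists that did not pass: DAM stage 1 (median 0.071, mean -0.023), lipid handling (median -0.10, higher direction), TREM2 signalling (median 0.046, mean -0.021) and endothelial markers (median -0.25, higher direction).

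The fifth comparison set the lines against each other after induction. Of 9663 genes 8 were higher and 4 lower in R47H, 1 of them a predicted gene that is not named. Ifi202b had 0 UMIs among 31566002 in WT induced and 1286 in R47H induced libraries, 1108 of them in R47H induced 1. Its mean was 14.4 ± 8.56 CPM (adjusted p = 0.00489), and a count of 0 allows up to 3 UMIs (0.095 CPM) over the WT group. The G protein subunit Gnb4 (ENSMUSG00000027669, chromosome 3, 32580332 to 32616585) rose from 0.436 ± 0.421 to 27.8 ± 8.93 CPM (log2 5.52, SE 0.93, adjusted p = 0.00752). Among R47H controls Gnb4 stood at 30.1 CPM in R47H control 6 and at a mean of 0.480 in the other 5. Ccdc80 rose from 1.69 ± 1.07 to 18.2 ± 11.5 CPM (3.31, SE 0.53, 0.00506). Slamf8, a receptor of myeloid cells (ENSMUSG00000053318, chromosome 1, 172581758 to 172590568), rose from 5.38 ± 3.40 to 34.0 ± 37.9 CPM (2.54, SE 0.51, 0.0408). The Fc receptor gene Fcgr4, uncertain for its near-identical relatives (ENSMUSG00000059089, chromosome 1, 171018920 to 171029761), rose from 11.4 ± 6.22 to 38.9 ± 16.7 CPM (1.76, SE 0.35, 0.0373). Fam167b (ENSMUSG00000050493, chromosome 4, 129576815 to 129578549) rose from 47.9 ± 19.7 to 148 ± 14.9 CPM (1.62, SE 0.25, 0.00489), and Hddc3 (ENSMUSG00000030532, chromosome 7, 80343104 to 80350547) from 4.27 ± 2.25 to 12.6 ± 5.00 CPM (1.66, SE 0.34, 0.0408). F11r, a junctional adhesion molecule (ENSMUSG00000038235, chromosome 1, 171437535 to 171464603), fell from 278 ± 32.4 to 134 ± 27.8 CPM (-1.06, SE 0.19, 0.014), and Ercc5 from 36.3 ± 10.5 to 20.7 ± 2.75 CPM (-0.81, SE 0.16, 0.0373). Each had 6 of 6 R47H libraries on the same side of the WT mean.

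**Figure D3:**
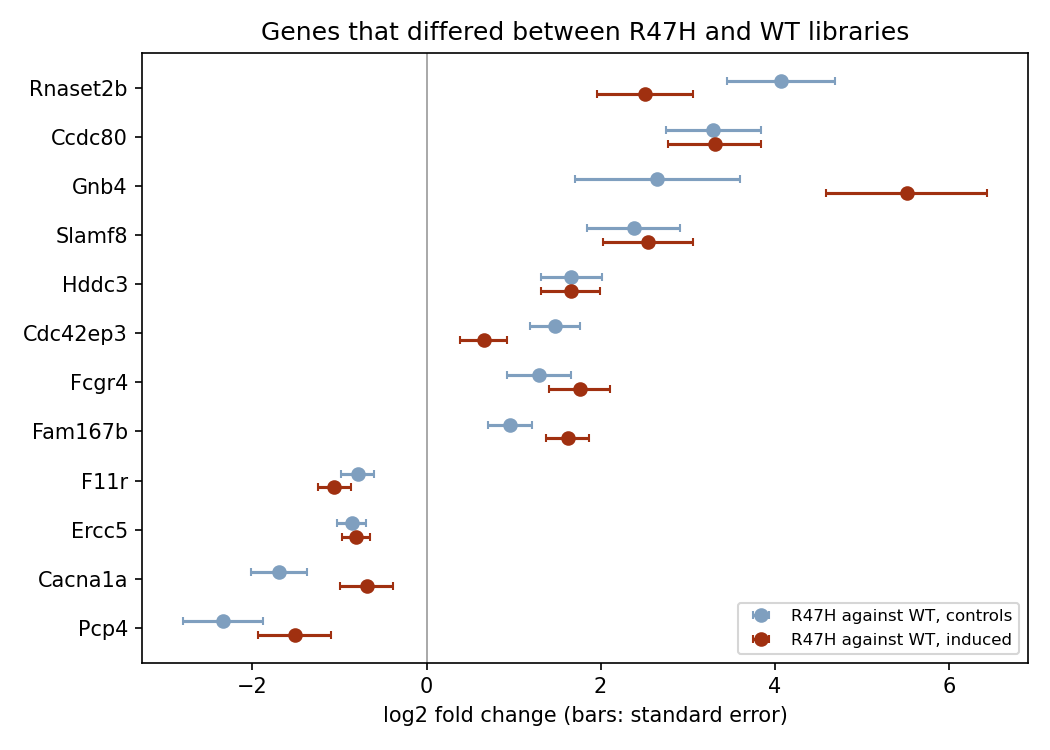
Log2 fold change of R47H against WT in summed microglia-like cells for genes that passed in controls or after induction, with controls in blue, induced libraries in red, bars for the standard error of the model and 6 libraries per group. Ccdc80 lies at 3.30 and 3.31 and Ercc5 at -0.86 and -0.81, while Gnb4 lies at 5.52 after induction.

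Epb41l3 (2.38, adjusted p = 0.00489) and Oscp1 (-2.19, SE 0.40, 0.0181) passed at means under 10 CPM. Rnaset2b, chosen after its values were seen, stood at 14.7 ± 25.2 and 89.9 ± 31.8 CPM (2.51, SE 0.55, adjusted p = 0.0694), with 66.1 CPM in WT induced 2. With the library quartet as a replicate block 32 genes passed, the 12 among them. Over the libraries other than the 4 deep ones, 19 genes passed. Fcgr4 then lost its call (log2 1.32, adjusted p = 0.106; 0.00117 to 0.15 over 27 alternatives), while Gnb4 (5.54), Ccdc80 (3.22), Slamf8 (2.20), Hddc3 (1.73), Fam167b (1.53), F11r (-0.91) and Ercc5 (-0.91) stood.

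The count of 12 genes between induced libraries became 6 without R47H induced 1, 7 without WT induced 4 and 19 without WT induced 2. Slamf8 lost its call without R47H induced 1 (1.64, adjusted p = 0.153) or any of WT induced 2 to 6 (0.0711 to 0.138). F11r lost it without R47H induced 1 (-0.98, 0.0516), and Oscp1 without WT induced 1 (0.0606) or R47H induced 4 (0.0605). Fcgr4 stood without WT induced 2 or R47H induced 2, 3, 4 or 5 and not without the others (0.0819 to 0.138). Ercc5 stood without WT induced 1, 3 or 6 or R47H induced 5 and not without the others (0.0613 to 0.129), and Hddc3 stood without WT induced 6 or R47H induced 2 or 5 and not without the others (up to 0.148). With only the induced groups in the fit, Slamf8 (0.237), Fcgr4 (0.15), Hddc3 (0.127) and Ercc5 (0.234) lost their calls, and so they did after thinning (0.0669, 0.118, 0.129 and 0.129). Ccdc80 lost it with voom (0.0502) and Fam167b under the stricter filter (1.45, 0.145). Over 27 alternatives adjusted p ran from 0.00032 to 0.237 for Slamf8, 0.00029 to 0.148 for Hddc3 and 0.00291 to 0.234 for Ercc5. Among genes that passed only with a library left out were H2-Aa (6.25, 0.00535), H2-Ab1 (5.10, 0.011) and Cd74 (5.55, 0.03) without WT induced 2, and H2-DMa without R47H induced 2 (1.19, 0.0241) or R47H induced 3 (1.15, 0.0461).

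MHC class II genes showed the widest difference between lines after induction among the 24 lists. All 6 were higher in R47H (median log2 3.77, adjusted p = 4.26e-15; adjusted p = 0.0201 with an estimated correlation), 5 of 6 passing adjusted over the list alone. Cd74 stood at 93.0 ± 137 and 1845 ± 3048 CPM (log2 4.29, SE 1.07, adjusted p = 0.16 over all genes), H2-Aa at 59.9 ± 114 and 1044 ± 1079 CPM (4.10, SE 1.05, 0.192), H2-Ab1 at log2 3.52 (SE 0.93, 0.213) and H2-DMa at 1.07 (SE 0.24, 0.0694). H2-Aa ranged from 81 to 2714 CPM over the R47H induced libraries. Without the 4 deep libraries the median was 2.65 (adjusted p = 1.92e-09; adjusted p = 0.187 with an estimated correlation), and without R47H induced 1 it was 2.74, with no list passing under an estimated correlation. By fry it was the 1 list in microglia that passed over all libraries (adjusted p = 0.0113; 0.0716 without the 4 deep libraries). The smallest fry adjusted p was 0.811 on WT induction, 0.72 on R47H induction, 0.812 for their difference and 0.17 between control libraries. With the quartet as a replicate block it was 4.27 (adjusted p = 3.27e-11; adjusted p = 0.138 with an estimated correlation). Under the loose filter the summed CPM of the list was 475.2 ± 962.5 in astrocyte-like, 273.0 ± 411.2 in endothelial-like and 5682 ± 7731 in microglia-like cells of R47H induced libraries (SD, n = 6), and 35.6 ± 38.3, 24.2 ± 23.2 and 548.7 ± 483.9 in those of WT induced libraries. Astrocyte-like cells of R47H induced libraries held 5.31% ± 3.56 of the microglial level, and 6.09% ± 1.82 of that of microglia markers, and endothelial-like cells 5.19% ± 3.55 and 5.01% ± 1.69.

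The DAM groups, interferon genes and energy metabolism were also higher in R47H after induction. All 16 DAM stage 2 genes (median 0.78, adjusted p = 3.55e-11; 2 adjusted over the list alone), were higher, such as Spp1 (2.71, SE 0.82) and Itgax (2.29, SE 0.73). So were 7 of 7 DAM stage 1 genes (0.51, 0.000901), such as Lyz2 (1.24, SE 0.51), and 14 of 14 interferon genes (0.81, 9.45e-07). So were 9 of 9 MHC class I genes (1.19, 6.71e-08; 6 adjusted over the list alone), such as H2-K1 (1.41, SE 0.41), and 10 of 10 glycolysis genes (0.52, 0.000425), such as Ldha (0.57, SE 0.19). Of 15 homeostatic genes 13 were lower (-0.19, 0.0125). These 6 lists had adjusted p = 0.339 with an estimated correlation. Lysosome (17 of 18, 0.33, 6.41e-05), lipid handling (8 of 12, 0.37, 0.0159), cholesterol synthesis (9 of 11, 0.22, 0.0125) and ribosomal genes (73 of 74, 0.38, 2.93e-12) were higher, with adjusted p = 0.389 with an estimated correlation for each. Cytokines and chemokines were higher in 8 of 11 (0.45, 0.0358; adjusted p = 0.418 with an estimated correlation), with Cxcl16 at 0.65 and Ccl2 at -0.74. Oxidative phosphorylation genes were higher in 21 of 22 (0.26, 0.000763; adjusted p = 0.467 with an estimated correlation; 1 adjusted over the list alone), such as Sdhb (0.46, SE 0.13). Astrocyte markers were lower (-0.34, 0.0488; adjusted p = 0.418 with an estimated correlation).

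**Figure D4:**
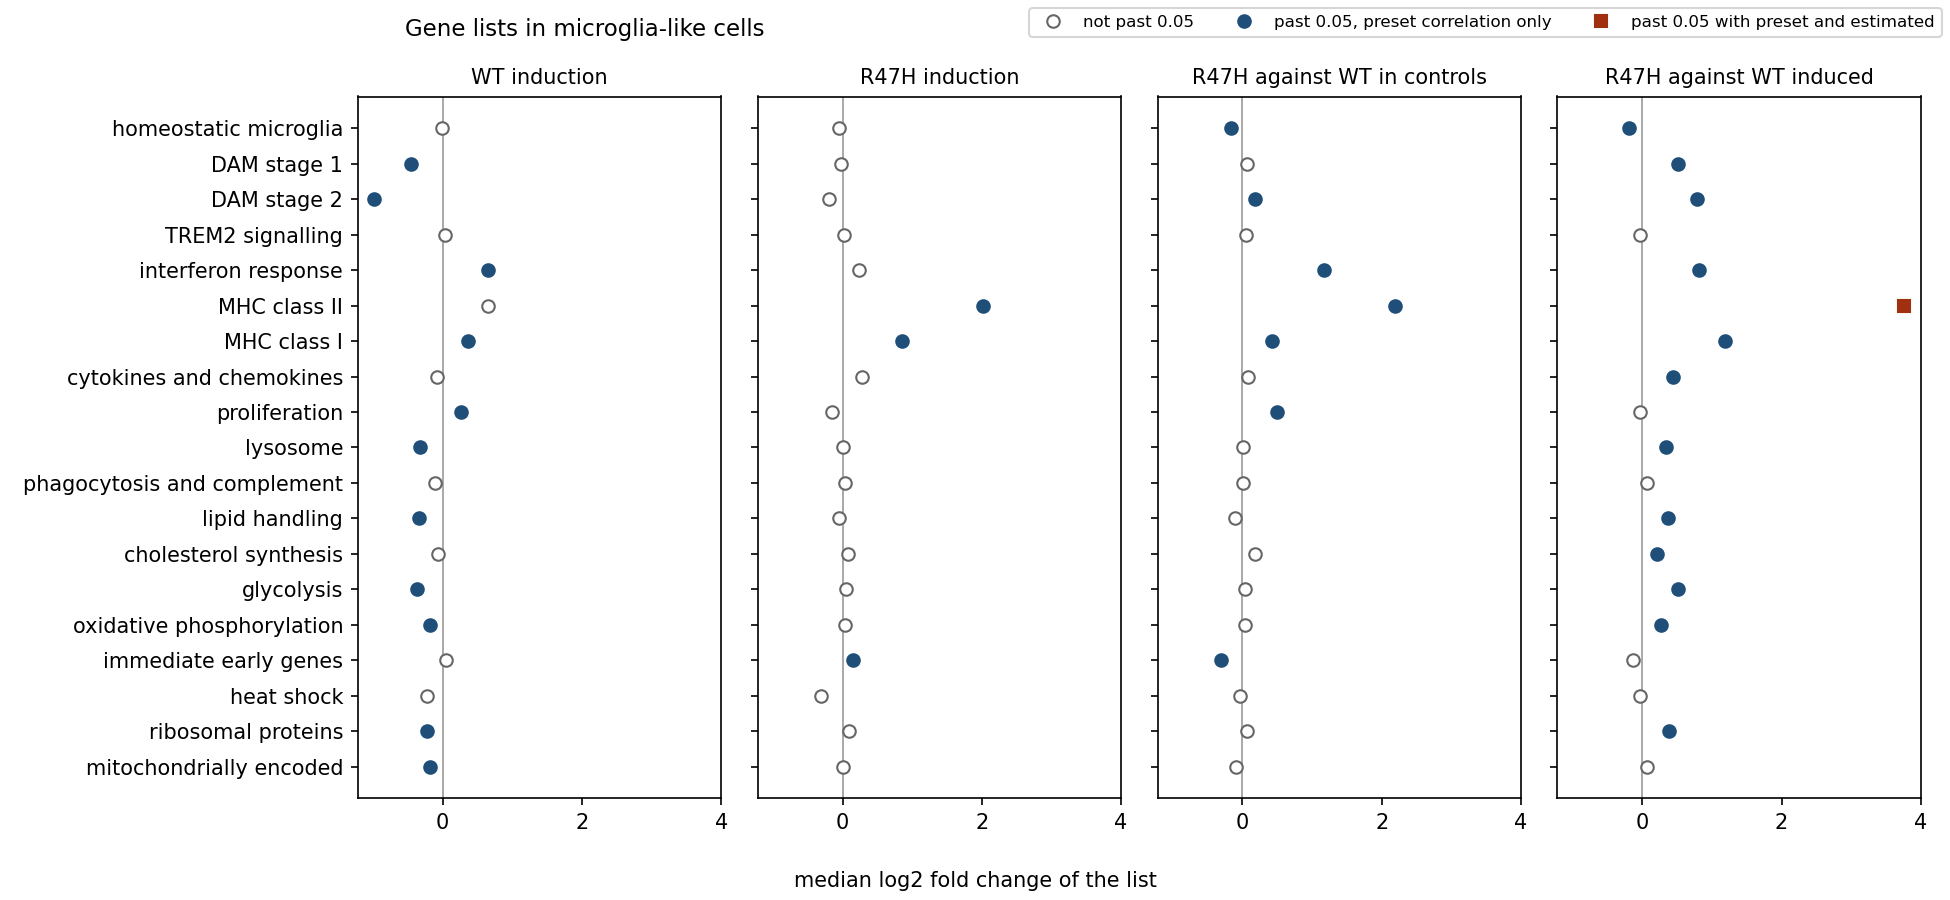
Median log2 fold change of the tested genes of 19 lists in microglia-like cells for 4 comparisons of 6 against 6 libraries, with open points for lists not past 0.05, filled circles for lists past 0.05 at the preset correlation and a square for the list also past 0.05 with an estimated one. MHC class II reaches 3.77, the square, for R47H against WT induced libraries, and DAM stage 2 reaches -0.98 on WT induction.

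Between induced libraries 11 lists passed without the 4 deep libraries, in place of 14, with adjusted p = 0.187 to 0.629 with an estimated correlation. DAM stage 2 was then at 0.65 (adjusted p = 3.93e-05), DAM stage 1 at 0.38 (0.0134), interferon at 0.48 (0.00381) and MHC class I at 0.57 (4.23e-05). Lysosome was at 0.23 (0.00381), glycolysis at 0.31 (0.00176), oxidative phosphorylation at 0.26 (3.51e-06), ribosomal at 0.35 (7.66e-18) and homeostatic at -0.18 (0.0197). Astrocyte markers (-0.425, 0.0534), cytokines (0.38, 0.321), lipid handling (0.19, 0.236) and cholesterol synthesis (0.13, 0.0602) then lost their calls, and immediate early genes gained one (-0.13, 0.0388; -0.14 and 0.102 over all libraries). With the quartet as a replicate block 15 lists passed, immediate early genes (-0.13, 0.0392; adjusted p = 0.391 with an estimated correlation) beside the former 14. Astrocyte markers lost their call also with Xist (0.0618), where lipid handling was at 0.555 (0.00207). Without R47H induced 1 astrocyte markers (0.0824) and lipid handling (0.40, 0.054) lost theirs, mitochondrial genes gained one (0.25, 0.00474), and MHC class I was at 0.56 (0.00101), lysosome at 0.105 (0.0417), glycolysis at 0.16 (0.0417), cholesterol synthesis at 0.12 (0.0274) and oxidative phosphorylation at 0.43 (2.27e-07). Without WT induced 1 the count was 8. Other lists that did not pass with all libraries included proliferation (-0.029, 0.612), heat shock (median -0.039, higher direction, 0.72), TREM2 signalling (median -0.037, mean 0.015, 0.88) and choroid plexus markers (-0.14, 0.9).

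Shares of cells were compared between groups with exact permutation tests. Microglia-like cells made up 84.8% ± 12.4 of cells in WT control, 79.6% ± 14.3 in WT induced, 75.5% ± 12.1 in R47H control and 77.6% ± 19.4 in R47H induced libraries (SD, n = 6 each). WT induction changed the share by -5.17 percentage points (exact p = 0.496; -4.35 and 0.167 without the 4 deep libraries) and R47H induction by 2.11 (exact p = 0.838; 5.55 and 0.302). R47H against WT gave -9.30 points in controls (exact p = 0.221) and -2.03 after induction (exact p = 0.773; -0.14 and 0.968 without the deep libraries). In controls the difference was -10.04 without the 4 deep libraries (exact p = 0.0317) and -14.10 without WT control 2 alone (exact p = 0.0238). Dissociation and dead cell removal can set such shares.

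**Figure D5:**
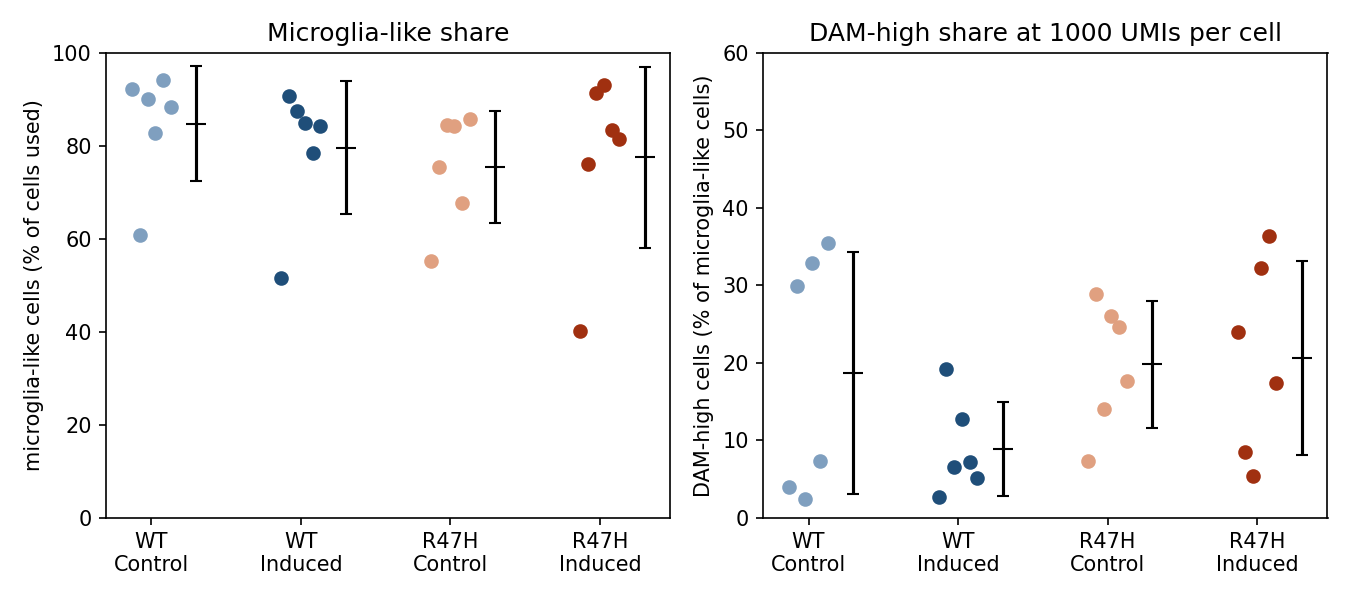
Share of microglia-like cells among cells used and share of DAM-high cells among microglia-like cells, in percent per library, for 4 groups of 6 libraries, with black bars for mean ± SD. DAM-high shares average 8.89% in WT induced libraries and 18.6% to 20.6% elsewhere, and the libraries of all groups overlap.

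DAM-high cells were 18.6% ± 15.6 of microglia-like cells in WT control, 8.89% ± 6.06 in WT induced, 19.8% ± 8.23 in R47H control and 20.6% ± 12.6 in R47H induced libraries (SD, n = 6 each). Unthinned shares were 18.9%, 8.75%, 20.3% and 21.2%. WT induction gave -9.74 points (exact p = 0.173; -6.25 and 0.421 without the 4 deep libraries) and R47H induction 0.83 (exact p = 0.898; -2.34 and 0.738), with a difference of 10.57 points between the inductions (permutation p = 0.259). R47H against WT gave 1.15 points in controls (exact p = 0.868; 5.88 and 0.452) and 11.72 after induction (exact p = 0.0693; 9.79 and 0.206). The last difference passed 0.05 without WT induced 2 (13.79, exact p = 0.0455), R47H induced 2 (14.15, 0.0411) or R47H induced 3 (14.78, 0.0238). Cells near the limit of the score made up 4.1%, 4.31%, 6.89% and 7.31% of the groups. The difference between inductions in the microglia-like share was 7.28 points (permutation p = 0.551).

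None of 22 tests of shares of single microglia-like clusters passed (smallest adjusted p = 0.918, exact permutation). The cluster led by Fos held 14.7% ± 13.3 of microglia-like cells in R47H control and 31.96% ± 20.1 in WT control libraries (exact p = 0.11; -20.67 points, exact p = 0.0476 without the 4 deep libraries).

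Endothelial-like and astrocyte-like cells, which lie outside the target of Cx3cr1CreER, served as a comparison for microglia. In endothelial-like cells 0 of 2054 genes passed on either induction with edgeR (9 and 17 at unadjusted p under 0.05 against 103 by chance) and 0 with DESeq2, in 4 libraries per group with at least 20 cells. Erythroid markers fell on WT induction (4 of 4, median log2 -2.29, adjusted p = 0.00131; adjusted p = 0.29 with an estimated correlation). They differed between the inductions (2.38, adjusted p = 0.001; adjusted p = 0.273 with an estimated correlation) and were lower in R47H than in WT controls (-1.17, adjusted p = 0.000871; adjusted p = 0.264 with an estimated correlation). Blood-brain barrier genes stood at 0.11 on WT induction (adjusted p = 0.613) and 0.10 on R47H induction (0.259). Microglia markers in these cells stood at 0.037 with a lower mean of -0.037 (0.614) and at -0.29 (0.492). Under the loose filter 0 of 8586 genes passed on either induction (64 and 69 at unadjusted p under 0.05; 429 by chance), and endothelial activation genes stood at -0.19 (0.181) and -0.12 (0.826).

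Between the lines under the loose filter, Rnaset2b (log2 3.89, SE 0.59), Ifi203 (2.25, SE 0.37) and Mndal (2.25, SE 0.37) were higher in endothelial-like cells of R47H controls, and the receptor gene Nrp2 (1.21, SE 0.21) in those of R47H induced libraries. Astrocyte-like cells, tested under the loose filter, gave 0 of 9335 genes on either induction with edgeR (48 and 86 at unadjusted p under 0.05; 467 by chance) and 0 with DESeq2. Robo2, an axon guidance receptor, was lower in R47H induced than in WT induced libraries (-2.87, SE 0.43, adjusted p = 0.00368). Reactive astrocyte genes fell on WT induction in 8 of 10 (median -0.31, adjusted p = 0.0381; adjusted p = 0.379 with an estimated correlation), such as Osmr (-0.81, SE 0.38) and Gfap (-0.55, SE 0.39). Microglia markers in the same cells (-0.21, adjusted p = 0.0186; adjusted p = 0.379 with an estimated correlation) and endothelial markers (-0.29, 0.0381; adjusted p = 0.379 with an estimated correlation) were lower beside them. On R47H induction reactive astrocyte genes stood at 0.13 (adjusted p = 0.998). After induction they were higher in R47H than in WT (0.34, adjusted p = 0.0225; adjusted p = 0.412 with an estimated correlation; 2 adjusted over the list alone). Homeostatic astrocyte genes stood at -0.058 (0.429) on WT and 0.011 (0.998) on R47H induction. By fry no list passed in these cells or in endothelial-like cells, with erythroid markers at adjusted p = 0.84 and reactive astrocyte genes at 0.587 on WT induction (smallest 0.479 in astrocyte-like and 0.355 in endothelial-like cells, 0.214 under the loose filter).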

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

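The splits of the groups were set before the data were examined. The endothelial test of Setd5, the astrocyte test of the line genes and the Xist test of MHC class II were chosen after the data had been seen, and before their own results were. The tests on the deep libraries, on runs of neighbouring genes, on chromosome clustering, on the values after induction, on R47H induced 1, on R47H induced 2, on free RNA, on border macrophage markers and on splits within pairs were chosen after their results or values like them were seen.

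Single libraries stood far from the other 5 of their group in 23 of 80 groups of values, where chance would give about 4 (a gap above 0.625 of the group's range). Total UMIs were 59657125 in WT control 2, 64114812 in WT induced 1, 57319503 in R47H control 1 and 73898385 in R47H induced 1. The same libraries gave 10913, 11933, 10279 and 11909 cells used. R47H induced 1 had the lowest median mitochondrial share of its group, 5.29% against a mean of 14.7% in the others. Microglia-like cells made up 60.82% of cells in WT control 2 (mean of the others 89.6%), 51.55% in WT induced 1 (85.2%) and 40.07% in R47H induced 1 (85.1%). Among genes that differed between lines, WT induced 2 had 66.07 CPM of Rnaset2b (mean of the others 4.43), 3.769 CPM of Ccdc80 (1.27) and 23.72 CPM of Fcgr4 (8.96). These values leave a doubt about its line label, although it had 0 UMIs of Ifi202b and 1.109 CPM of Gnb4, in the range of the other WT libraries, and every comparison between induced lines rests on that label. WT induced 1 had 342.2 CPM of F11r (265) and 11.93 of Slamf8 (4.07), WT induced 6 had 8.583 of Hddc3 (3.40), and WT control 1 had 79.98 of Fam167b (42.8). In the R47H groups, Gnb4 was at 30.1 CPM in R47H control 6 (0.480), Hddc3 at 22.52 in R47H induced 4 (10.6), and Ifi202b at 31.25 (11.02) and Slamf8 at 110.6 (18.7) in R47H induced 1.

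The inductions differed between lines for 10 lists by the test of the difference itself. The medians of the difference were -2.75 for choroid plexus markers, 0.712 for DAM stage 2, -0.383 for interferon response, 0.639 for MHC class II, 0.496 for MHC class I, -0.427 for proliferation, 0.317 for lysosome, 0.209 for oxidative phosphorylation, 0.178 for immediate early genes and 0.303 for ribosomal proteins. No list differed with an estimated correlation, and 16 of 100 splits gave as many lists (10; highest of the others 17), so chance was not excluded.

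Setd5 was higher in induced microglia of either line, and its neighbours Thumpd3 and Gt(ROSA)26Sor had higher values beside it. An effect of the treatment on all cells, such as tamoxifen itself, is argued against by endothelial-like cells under the loose filter, where the mean log2 fold of Setd5 over both inductions was -0.04 (SE 0.075) against 0.974 in microglia. The 4 deep libraries alone are argued against by the largest adjusted p without them, 0.00953. On WT induction these 3 genes around the ROSA26 locus of chromosome 6 topped 9602 runs of 3 neighbouring tested genes. On R47H induction they ranked 3. The 17 other neighbours lay between -0.34 and 0.44, yet Setd5 with Mtmr14 and Brpf1 among these ranked 5 and 28. Setd5 alone can lift a run, so the ranks do not show that all 3 rose. A transgene placed in the ROSA26 locus is a candidate that was not tested, since its site is not given in the sources used here. Tamoxifen acting in microglia alone stays open.

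Genes that differed between the R47H and the WT line may be inherited variants of one line, clustered on chromosomes. Among 38 genes with p under 0.001 in controls, 11 pairs lay within 5 Mb, against a mean of 4.04 in random sets (highest 21, 90 of 10000 sets with as many, permutation p = 0.009). A different state of the microglia in the R47H libraries of one treatment is argued against for 8 of the 9 genes called in controls, which had the same direction and p under 0.05 after induction. It stays open for Adgrg5 (-4.86 in controls and -0.74 after induction), Gnb4 (27.8 CPM in R47H induced and 0.480 in R47H control libraries other than R47H control 6) and Oscp1 (-2.19 after induction and -0.75 in controls). Inherited variants acting in every cell type cannot be told apart from effects in microglia, since 6 of 8 genes had the same direction in astrocyte-like cells, 3 of them with p under 0.05 (Rnaset2b at 2.76, Hddc3 at 1.005 and F11r at -1.12), and an effect of the R47H form before induction stays open, as untested, because line and form always went together.

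MHC class II genes were higher in R47H than in WT induced libraries (median log2 3.77). They were higher in controls too, by less with all libraries and by no less without the 4 deep ones. Whether induction adds to the difference stays open. R47H induced 1 alone is argued against by the median without it, 2.739, which is above 1.88, the level of 0.5 of the value with all libraries. Sex of the animals, read from Xist, is argued against by a median of 4.583 (mean SE 0.811) with Xist as a covariate, and of 4.758 (0.817) without R47H induced 2, whose sex neither Xist nor Y genes tell. Free RNA present alike in all droplets is argued against by the level of the list in astrocyte-like or endothelial-like cells of R47H induced libraries, at most 11.59% of that in microglia-like cells. Border macrophages counted among the microglia-like cells cannot be told apart, since the log2 ratio of their summed markers was 0.899 (SE 0.647) and 1 of 7 markers was high enough to be tested, and a difference between the lines and an effect of the R47H form stay open beside it.

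The other splits of the same libraries bear on the counts of calls. For genes, 2 of 100 splits, the real one counted, gave as many on R47H induction (2, highest of the others 4). Between the lines 1 did in controls (9, 1) and 2 when induced (12, 14). So few argue against chance only where libraries can be exchanged freely. On WT induction 6 did (1, 32), so chance was not excluded. Among the 32 splits that part all 6 pairs of a quartet, 1 gave as many on R47H induction (2; 1) and 3 with the block (1; 2), and between induced lines 1 did (12; 1) and 1 with the block (32; 3), so chance was not excluded for R47H induction with the block. The difference between inductions had 0 genes, a count that all 100 of 100 splits reach by construction, so the splits do not bear on it, and the highest of them gave 1826. Splits with 32 and 1826 genes point to a structure other than the groups, so free exchange is doubtful. For lists chance was not excluded in any comparison: 19 of 100 splits gave as many on WT induction (11; highest of the others 17), 92 on R47H induction (3; 16), 40 between control libraries (9; 14) and 9 between induced libraries (14; 15). The same holds for the counts of 0 on either induction in endothelial-like cells (35 of 35 splits, highest 0) and in astrocyte-like cells under the loose filter (100 of 100, highest of the others 2 and 1), where the splits bear on nothing.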

How the results depend on the processing

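Alternatives chosen after seeing the data were those on the 4 deep libraries, the loose cell filter, the automatic doublet limit, Xist as a covariate for lists (also without R47H induced 2, where 15 lists passed between induced libraries), libraries left out in endothelial-like cells, the block for the lists of the difference between inductions and of the lines, and all alternatives of shares between lines and of astrocyte-like cells. Of the counts and shares, 307 values kept their size or call, 81 counts moved by over 1.5 times, 20 shares reversed and 6 shares passed newly. For single genes 6030 values kept direction and call, 129 lost a call, 121 gained one and 39 reversed. RLE scaling and kept doublets moved no count of genes by over 1.5 times. The cause was not tested for the values below, except where fewer cells, libraries or tested genes are the setting itself. Depth limits low genes most: the shallowest microglia-like sum held 1208245 UMIs, where 1 UMI is close to 1 CPM.

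For WT induction, the count of 1 gene became 3 with DESeq2, voom, the loose filter or without the 4 deep libraries, 2 with Xist or with the deep libraries as a term, and 0 under the stricter filter. The 2 genes of R47H induction became 1 at a minimum of 10 CPM, after thinning, without the deep libraries or under the loose filter, 0 with only the groups compared or the stricter filter, and 7 with the deep libraries as a term. The 9 genes between control libraries became 36 with DESeq2, 44 with voom, 33 without the deep libraries, 42 with them as a term, 5 with only the groups compared, 4 after thinning and 1 under the stricter filter. The 12 genes between induced libraries became 49 with DESeq2, 33 with voom, 30 with Xist, 19 without the deep libraries, 37 with them as a term, 6 after thinning and 1 under the stricter filter. With each library left out in turn the counts ran from 1 to 3 on WT induction, 0 to 1 on R47H induction, 0 to 1 for the difference between inductions, 5 to 11 between control and 6 to 19 between induced libraries. In endothelial-like cells, no filter on low counts gave 3 genes on WT induction (all lower, smallest adjusted p = 0.00662) and 22 on R47H induction (21 higher, smallest adjusted p = 0.00204) over 19115 genes.

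For lists, an estimated correlation left 0 on WT induction, R47H induction, their difference and between control libraries, and 1 between induced libraries. Without the deep libraries there were 8 on R47H induction, 5 for the difference and 15 between control libraries. With each library left out, passing lists ran from 6 to 13 on WT induction, 2 to 10 on R47H induction, 6 to 14 for the difference, 7 to 14 between control and 8 to 15 between induced libraries.

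Of pairs of libraries within the quartets used as a replicate block, 30 of 36 had deviations correlated above 0.1 (from -0.4 to 0.96). Closest to their own quartet were 19 of 24 libraries, a hint from the data. The 6 pairs below 0.1 all held WT control 1 or WT control 2. The 4 deep libraries, WT control 2 among them although its number is not that of the others, correlated at 0.85 to 0.96 with each other, again only a hint, and no number was exchanged. Comparisons with WT control libraries stand unpaired, since not all of their pairs passed 0.1. With the replicate block, 3, 1, 26 and 32 genes passed on WT induction, R47H induction, between control and between induced libraries, and 6, 4, 34 and 57 without the deep libraries. The replicate block gave 5 lists on R47H induction and 15 between induced libraries, and changed no other call of a list in these comparisons at the preset correlation. On R47H induction it ended the call of Adgrg5 (0.0787), and between induced libraries that of MHC class II with an estimated correlation (0.138). It moved Gpnmb between control libraries to 0.059, and to 0.85 without the deep libraries, with Trem2 on R47H induction at -0.10.

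The microglia-like share between control libraries passed without the deep libraries (-10.04, exact p = 0.0317). With libraries left out, its differences ran from -9.96 to 0.44 on WT induction, -1.95 to 9.61 on R47H induction, -14.10 to -5.25 between control and -7.64 to 5.48 between induced libraries, where it was 4.07 under the stricter and 3.30 under the loose filter. The DAM-high share on R47H induction was -6 when thinned to 2000 UMIs, -2.34 without the deep libraries and -2.33 to 3.89 with libraries left out. Between control libraries it was -1.47 when DAM UMIs had to exceed 2 times the homeostatic ones, and -2.11 to 4.51 with libraries left out. Between induced libraries it was 9.94 without Apoe in the score (exact p = 0.039) and 8.55 to 14.78 with libraries left out.

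Reversed single genes were these. With voom, Itgax (0.11) and Pgk1 (0.061) turned on WT induction, Trem2 (-0.17) on R47H induction, Gpnmb (-0.16) and Itgax (-1.11) in the difference, and Trem2 (0.018) and Gpnmb (1.94) between control libraries. Under the stricter filter, Npc2 (0.083) turned on WT induction, Trem2 (-0.097) on R47H induction, Spp1 (-0.41), Npc2 (-0.18) and Gusb (-0.036) in the difference, Trem2 (0.17) and Siglech (0.059) between control and Apoe (-0.081) between induced libraries. Without the deep libraries, Trem2 (-0.073) turned on R47H induction, H2-DMb1 (-0.008) and H2-Ab1 (-0.44) in the difference, and Trem2 (0.029), Lilrb4a (0.047) and Gpnmb (1.10) between control libraries. Under the loose filter, Trem2 turned on R47H induction (-0.065) and between control libraries (0.02), as did Gpnmb there (0.28). With libraries left out, Pkm ran from -1.21 to 0.28 on WT induction (positive without WT control 2), Trem2 from -0.093 to 0.15 on R47H induction and from -0.18 to 0.038 between control libraries, Gpnmb there from -0.97 to 0.77 (positive without WT control 2) and H2-DMb1 in the difference from -0.38 (without R47H induced 1) to 1.07.

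The astrocyte tests under the main filter, with 1 library per group holding enough cells, and the oligodendrocyte tests, with no cluster, were not run.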

Other observations

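These values were looked at after the comparisons, and none was tested. Immune cells other than microglia-like cells came mostly from 1 library. T or NK-like cells numbered 641, with 53.5% of them in R47H induced 1. An unnamed cluster of 1743 cells, led by Ms4a7 and the MHC class II gene H2-Eb1, took 97.2% of its cells from the same library. A microglia-like cluster of 1043 cells led by the chemokines Ccl12 and Cxcl13 took 41.4% of its cells from R47H induced 6.

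Xist, transcribed from the inactive X chromosome of females, and genes of the Y chromosome divided the microglia-like sums within every group. Replicates 2, 4 and 6 of a group had 1851.9 to 3237 CPM of Xist, and replicates 1, 3 and 5 had at most 4, with 1 exception. R47H induced 2 had 0.9 CPM of Xist and 6.4 CPM of Y genes, low in both. WT control 2, a deep library, was high in both, at 116.6 CPM of Y genes against 3.2 to 21.3 in the other libraries with high Xist. Whether WT control 2 holds cells of more than 1 mouse or carries a wrong label is left open. It supplied 23756136 of the 39138218 microglia-like UMIs of WT control libraries.

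DAM-high shares of WT control libraries divided along the same numbers, with 29.9%, 32.9% and 35.5% of microglia-like cells in replicates 2, 4 and 6 and 3.98%, 2.37% and 7.26% in replicates 1, 3 and 5. R47H control libraries had 28.9%, 26.03% and 17.7% against 7.34%, 14.1% and 24.6%. WT induced libraries had 19.2%, 12.7% and 5.13% against 2.65%, 6.50% and 7.15%, and R47H induced libraries 8.42%, 32.2% and 17.3% against 24.02%, 5.31% and 36.4%. The fall on WT induction thus lay in replicates 2, 4 and 6, a division that the exact tests did not use.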
